A study of Homo sapiens with 15 samples.

How the data were processed

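RNA was sequenced from 15 libraries of human embryonic stem cells, 3 in each of 5 groups. The source label says embryonic stem cells while the growth protocol names both the H9 line and induced pluripotent cells, so H9 was assumed. Per the labels, cells grew on a layer of mouse embryonic fibroblasts, total RNA was depleted of ribosomal RNA with a stranded kit, and libraries were read on an Illumina HiSeq. The groups were cells in medium with 10 ng/mL FGF2 (FGF2 medium), cells in medium without FGF2 (no FGF2), and cells under blue light whose titles carry 1 min, 5 min or 10 min (light 1 min, light 5 min, light 10 min). The labels do not say whether these minutes are a length or an interval of illumination. The medium label of the light groups also lists 10 ng/mL FGF2, and whether FGF2 was present in those cultures could not be settled from the labels.

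The deposited files hold raw counts per Ensembl gene ID, whole numbers with no scaling by the authors found in them. Per the submitters' processing notes the authors used bcl2fastq 2.17.1.14, FastQC 0.11.5, TopHat2 2.0.9, SAMtools and HTSeq 0.9.1 with build hg19/GRCh37. The strand setting, annotation release and filters are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene therefore cannot be told apart, and neither can reads shared with near-identical copies, which concerns POU5F1, NANOG and KRT18 in particular. Reads from mouse feeder RNA were not separated here. Each file lists 57773 gene IDs and no row for unassigned reads. Symbols were taken by gene ID from tables of names and matched 52338 IDs, which held 94.84% of the counts. No coordinates are given because the annotation used for names is of another build.

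Totals per library ran from 11060549 to 37353960 counts. A count of 0 allows up to 3 counts, which is 0.0803 CPM in the deepest library and 0.271 CPM in the shallowest. Intervals and floors of this kind cover counting error only. Since nothing in the labels says that replicates came from separate cultures, p-values measure only the spread between these libraries, which may be technical. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom between their counts was 3.82 or more in each of the compared pairs.

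Genes were kept with edgeR's filterByExpr, which left 18363, and scaled by TMM. All 15 libraries entered 1 fit of group means, and each pair of groups was compared with edgeR's quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg over all genes tested, and genes under 0.05 are called changed. Counts at 2-fold or more are given beside these. Fold changes are log2 and levels are TMM-scaled CPM as mean ± SD. Standard errors, printed for some fold changes, were back-calculated as the absolute log2 change divided by the square root of the F statistic. Before the data were examined, 32 gene lists were fixed. They were tested with limma's camera on log2 CPM (prior count 2) at an inter-gene correlation of 0.01, adjusted over 320 tests, and again with an estimated correlation and with fry. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15.

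Genes named in the text follow a rule fixed before the data were examined. It takes POU5F1, NANOG, SOX2, DUSP6, SPRY2, SPRY4, ETV4, ETV5, EGR1, FOS, FGFR1, PAX6, GATA3, T and SOX17 always, of which T and SOX17 did not pass the filter. It adds the 6 largest rises and 6 largest falls per comparison (3 and 3 between light groups) among called genes with at least 3 CPM in the higher group and no overlap between the libraries of the groups, and up to 4 members with the smallest adjusted p of each list discussed. Mitochondrial, small RNA, pseudogene and unnamed genes were left out of the second part. Not every gene of the first part is printed for every comparison. Chance alone separates 3 libraries from 3 without overlap for 10% of genes.

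The edgeR test was checked on simulated counts for no FGF2 against FGF2 medium over 18363 genes with 200 changed: it recovered 63.6% of 2-fold and 85.7% of 4-fold changes, and 5.2% of its calls fell on unchanged genes. An unchanged pair of groups gave 0 calls there.

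Alternatives planned before the data were examined covered scaling, filters, a replicate block, flow cell, the test, the threshold, the samples in the fit and leaving out each library. Ranges of gene counts and of shares higher cover, when a library is left out, only libraries of the groups compared. Added after seeing the data were a term for library composition and a fit without part of the libraries. These rest on the share of counts held by 2 abundant gene IDs without a symbol, which was over 5% in 6 libraries (2 each of FGF2 medium, light 1 min and light 5 min) and lower in the other 9, the low-share libraries. That fit keeps 1 library each of FGF2 medium, light 1 min and light 5 min, assumed to vary like the other groups.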

Results

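The series concerns optical stimulation of FGF signalling as a way to keep human pluripotent stem cells undifferentiated. Transcript counts were compared among human embryonic stem cells in FGF2 medium, cells without FGF2 and cells under blue light labelled 1, 5 or 10 min, with 3 libraries per group and totals of 11060549 to 37353960 counts. The first principal component held 46.7% of the variance and the second 12.6%.

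**Figure D1:**
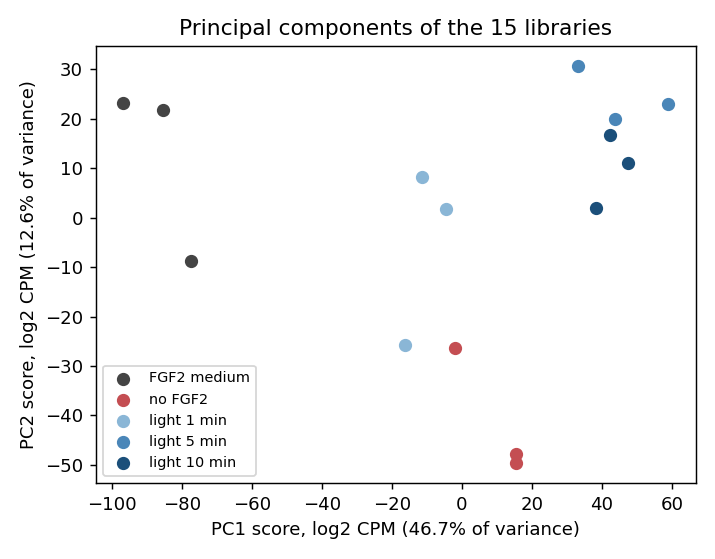
Principal component scores of the 15 libraries on log2 CPM, 1 point per library, coloured by group. FGF2 medium lies at 1 end of the first axis (46.7% of variance) and light 5 min and light 10 min at the other, with no FGF2 and light 1 min between.

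The first comparison asks what leaving out FGF2 did. Pluripotency genes fell. POU5F1 (ENSG00000204531), which encodes the transcription factor OCT4, went from 282 ± 70.0 to 39.8 ± 2.59 CPM (SD, n = 3 each), a log2 change of -2.82 with a standard error of 0.32 (edgeR adjusted p = 8.3e-06). NANOG (ENSG00000111704), another core factor, went from 34.2 ± 3.25 to 5.26 ± 0.733 CPM, a log2 change of -2.69 (edgeR adjusted p = 3.29e-05). SOX2, shared by pluripotent and neural cells, was at 180 ± 42.6 and 169 ± 48.5 CPM (edgeR adjusted p = 0.725). Of the 29 tested genes of the pluripotency list, 24 fell, SFRP2, a secreted WNT modulator, alone rose and 4 were not called, with a median log2 change of -1.73. The counts adjusted over the list alone were 24 lower and 1 higher. The list as a whole was lower (camera adjusted p = 5.17e-11, and adjusted p = 0.386 with an estimated correlation).

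FGF targets split. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, dropped from 83.6 ± 3.21 to 18.8 ± 1.81 CPM (log2 change -2.15, edgeR adjusted p = 1.71e-08). ETV4, an ETS factor induced by FGF, dropped from 43.3 ± 3.65 to 8.02 ± 0.955 CPM, and DUSP6, an ERK phosphatase, from 187 ± 1.06 to 92.7 ± 17.4 CPM. SPRY2 libraries were at 78.2, 74.6 and 70.1 CPM in FGF2 medium and lower, at 43.1, 39.4 and 41.5 CPM, without FGF2. Libraries overlapped for ETV5, at 42.5, 48.5 and 43.6 against 48.8, 35.3 and 44.2 CPM. They also overlapped for FOS, at 27.5, 24.8 and 29.4 against 41.1, 25.5 and 25.2 CPM. GATA3, a lineage gene, was at 8.03, 5.05 and 4.54 against 6.86, 7.89 and 7.86 CPM, also overlapping. In the FGF and ERK target list 10 of 25 genes fell and DUSP4, SPRED2, EGR1 and SPSB1 rose. Adjusted over the list alone, 12 fell and 4 rose (camera adjusted p = 0.022, and adjusted p = 0.608 with an estimated correlation). FGFR1, the receptor, whose counts could include a receptor construct, went from 264 ± 42.6 to 185 ± 26.6 CPM (log2 change -0.51, edgeR adjusted p = 0.00339).

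Some lineage genes rose in the same libraries. PAX6, a factor of neural and eye development, went from 40.7 ± 19.9 to 364 ± 63.8 CPM (log2 change 3.16, edgeR adjusted p = 3.83e-07). In the neural ectoderm list 11 of 27 genes rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00137, and adjusted p = 0.619 with an estimated correlation). Among 18 mesoderm genes 10 rose, with PDGFRA going from 17.8 ± 3.42 to 72.3 ± 13.0 CPM, while KDR fell from 85.8 ± 4.06 to 16.8 ± 3.16 CPM (camera adjusted p = 0.00678, and adjusted p = 0.327 with an estimated correlation). Of 14 BMP targets 6 rose and 0 fell, with SMAD9 going from 5.68 ± 1.54 to 44.7 ± 6.52 CPM (camera adjusted p = 0.0191, and adjusted p = 0.386 with an estimated correlation), a call lost without no FGF2 replicate 3 (camera adjusted p = 0.0758). Genes higher and lower were 3 and 4 of 15 for neural crest, 3 and 2 of 13 for endoderm, 1 and 0 of 10 for primitive streak, 7 and 4 of 21 for trophoblast and amnion, 3 and 3 of 9 for endothelium and blood, and 1 and 5 of 16 for surface epithelium (lowest camera adjusted p = 0.122). Glycolysis and hypoxia genes fell in 20 of 27 cases, with ADM going from 146 ± 36.8 to 29.2 ± 6.57 CPM (camera adjusted p = 2.65e-07, and adjusted p = 0.327 with an estimated correlation).

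The 6 largest rises without FGF2 included CRYAA, a lens crystallin, from 0.154 ± 0.127 to 94.6 ± 101 CPM, whose libraries were at 2.30, 79.6 and 202 CPM, and MAB21L1, a gene of eye development, from 0.244 ± 0.103 to 67.9 ± 39.0 CPM. HSD17B2, a steroid dehydrogenase, went from 0.246 ± 0.0622 to 22.5 ± 3.97 CPM. Among the 6 largest falls were TM4SF18, from 21.6 ± 3.39 to 0.370 ± 0.171 CPM, and LINC00458, a long noncoding RNA, from 26.2 ± 6.71 to 0.157 ± 0.136 CPM. In all, edgeR called 7809 of 18363 genes, 3948 higher and 3861 lower without FGF2, and 2594 of them changed at least 2-fold. The share higher ran from 45.0% to 57.4% over the alternatives. The count was 2964 with the low-share libraries only, an alternative chosen after seeing the data that leaves 1 library of FGF2 medium, which is then assumed to vary like the other groups.

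**Figure D2:**
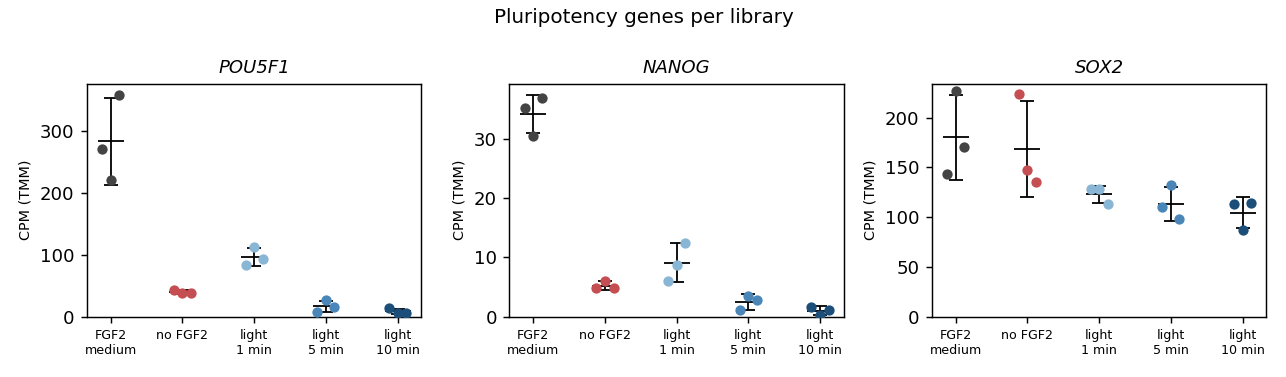
CPM of POU5F1, NANOG and SOX2 in each library by group, with points for libraries and bars for mean ± SD (n = 3). Mean POU5F1 is 282 CPM in FGF2 medium, 39.8 without FGF2, and 96.6, 17.1 and 8.82 in light 1, 5 and 10 min.

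Light 1 min against no FGF2 asks whether this light label differed from FGF2 withdrawal. POU5F1 rose from 39.8 ± 2.59 to 96.6 ± 14.4 CPM (log2 change 1.28, SE 0.31, edgeR adjusted p = 0.0242), while NANOG was at 5.26 ± 0.733 and 9.06 ± 3.26 CPM (edgeR adjusted p = 0.17). The POU5F1 call was lost without no FGF2 replicate 1, no FGF2 replicate 2 or light 1 min replicate 2 (log2 changes 1.36, 1.27 and 1.16, edgeR adjusted p = 0.0609, 0.0722 and 0.098). In the pluripotency list 9 of 29 genes rose, among them ZFP42, a zinc finger factor, from 62.4 ± 1.70 to 122 ± 13.6 CPM and PODXL, a surface sialomucin, from 217 ± 9.88 to 446 ± 101 CPM, and SFRP2 fell. Adjusted over the list alone, 13 rose and 2 fell (camera adjusted p = 7.3e-05, and adjusted p = 0.619 with an estimated correlation). Of this list 4 rose and 0 fell with library composition as a term, 10 and 0 with the low-share libraries only, both chosen after seeing the data, and 6 and 0 without the second flow cell, so the SFRP2 call was lost in each. In the naive pluripotency list 7 of 12 genes rose and 0 fell, with DNMT3L, a cofactor of DNA methylation, going from 0.0974 ± 0.0897 to 1.57 ± 0.938 CPM (camera adjusted p = 0.000262, and adjusted p = 0.384 with an estimated correlation).

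FGF targets did not move together here. ETV4 rose from 8.02 ± 0.955 to 14.8 ± 1.19 CPM, while SPRY4 fell from 18.8 ± 1.81 to 12.4 ± 1.03 CPM and DUSP6 from 92.7 ± 17.4 to 66.3 ± 8.79 CPM. The SPRY4 call was lost without no FGF2 replicate 2 or light 1 min replicate 2 (edgeR adjusted p = 0.0725 and 0.0743), and the DUSP6 call without no FGF2 replicate 1, no FGF2 replicate 3 or light 1 min replicate 2 (edgeR adjusted p = 0.0592, 0.0527 and 0.111). In the list 1 gene rose and 4 fell of 25, or 2 and 9 adjusted over the list alone (camera adjusted p = 0.0369, and adjusted p = 0.619 with an estimated correlation). Without no FGF2 replicate 3, light 1 min replicate 2 or light 1 min replicate 3 the camera adjusted p were 0.336, 0.0664 and 0.0585. Of 27 neural ectoderm genes 5 fell and 0 rose, with SIX3 going from 25.1 ± 3.98 to 10.4 ± 1.87 CPM (camera adjusted p = 0.00018, and adjusted p = 0.589 with an estimated correlation). COL3A1, a fibrillar collagen, rose from 63.6 ± 10.8 to 322 ± 72.6 CPM, one of 7 of 30 fibroblast and matrix genes that rose with 0 falling (camera adjusted p = 0.00116, and adjusted p = 0.619 with an estimated correlation). With the composition term, with the low-share libraries only and without the second flow cell, 2, 1 and 4 FGF and ERK targets, and 3, 6 and 5 neural ectoderm genes, fell, and 6, 4 and 9 fibroblast and matrix genes rose. CDX4, a posterior homeobox gene, had 5.80 ± 2.97 CPM in light 1 min and 0 counts in the 3 libraries without FGF2, which allows up to 0.271 CPM in the shallowest of these.

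EdgeR called 1229 genes, 660 higher and 569 lower in light 1 min, and 375 at 2-fold or more (211 higher and 164 lower). The share of calls that were higher ran from 47.1% without no FGF2 replicate 3 to 82.4% at a threshold of 1.5-fold, so neither direction prevailed throughout. Single libraries moved the count of genes, to 650, 299 and 3463 without light 1 min replicates 1, 2 and 3, and to 479 and 523 without no FGF2 replicates 1 and 2. It was 530 with library composition as a term and 462 with the low-share libraries only, alternatives chosen after seeing the data, and 1903 with a flow cell term and 2042 without the libraries of the second flow cell, which were planned.

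Light 5 min against no FGF2 showed lower pluripotency genes. POU5F1 fell from 39.8 ± 2.59 to 17.1 ± 9.05 CPM (log2 change -1.22, SE 0.32, edgeR adjusted p = 0.0168), and NANOG was at 5.26 ± 0.733 and 2.48 ± 1.28 CPM (edgeR adjusted p = 0.0572). The POU5F1 call was lost without no FGF2 replicate 1, light 5 min replicate 1 or light 5 min replicate 3 (log2 changes -1.13, -0.88 and -1.18, edgeR adjusted p = 0.0546, 0.0502 and 0.0526). Of 29 pluripotency genes 21 fell and 0 rose, with a median log2 change of -1.08, and 23 fell when adjusted over the list alone (camera adjusted p = 1.65e-10, and adjusted p = 0.386 with an estimated correlation). DNMT3B, a DNA methyltransferase, went from 178 ± 42.4 to 64.2 ± 15 CPM and L1TD1, an RNA-binding protein, from 197 ± 19.4 to 43.6 ± 18.9 CPM. Surface epithelium genes fell in 13 of 16 cases and 0 rose, with CDH1, which encodes E-cadherin, at 122 ± 21.3 and 18.0 ± 13.5 CPM and EPCAM at 54.6 ± 7.01 and 23.1 ± 4.94 CPM (camera adjusted p = 5.06e-07, and adjusted p = 0.418 with an estimated correlation). Of 21 trophoblast and amnion genes 9 fell and 1 rose, with KRT7, a keratin, going from 34.2 ± 4.86 to 12.8 ± 5.04 CPM (camera adjusted p = 0.000358, and adjusted p = 0.589 with an estimated correlation).

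Matrix genes rose in light 5 min. COL3A1 was at 63.6 ± 10.8 and 325 ± 54.2 CPM without FGF2 and in light 5 min (log2 change 2.36, edgeR adjusted p = 1.89e-05), and 16 of 30 fibroblast and matrix genes rose and 1 fell (camera adjusted p = 6.79e-08, and adjusted p = 0.384 with an estimated correlation). SPRY4 fell from 18.8 ± 1.81 to 10.3 ± 0.882 CPM, CCND1, a cyclin, rose from 367 ± 37.3 to 539 ± 17.3 CPM, and the FGF and ERK target list had 5 rising and 3 falling genes of 25 (camera adjusted p = 0.843). FGFR1 fell from 185 ± 26.6 to 116 ± 9.81 CPM. The 6 largest rises included SOST, a secreted inhibitor of WNT signalling, from 5.91 ± 6.31 to 33.4 ± 0.988 CPM, and GDF7, a BMP ligand, from 1.76 ± 1.26 to 10.1 ± 2.67 CPM. The 6 largest falls included HESX1, a forebrain factor, from 15.1 ± 6.15 to 1.36 ± 0.828 CPM, and GRHL2, an epithelial factor, from 27.1 ± 4.85 to 3.21 ± 2.87 CPM. EdgeR called 3154 genes, 1365 higher and 1789 lower in light 5 min, and 1000 at 2-fold or more (258 higher and 742 lower). The share of calls that were higher ran from 22.5% at a threshold of 1.5-fold to 52.9% with no low count filter, so neither direction prevailed throughout. The count was 1978 and 1889 without no FGF2 replicates 1 and 2, and 2002, 1910 and 1913 without light 5 min replicates 1, 2 and 3. It was 1680 with library composition as a term and 1482 with the low-share libraries only, both chosen after seeing the data.

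Light 10 min against no FGF2 also showed lower pluripotency genes. POU5F1 fell from 39.8 ± 2.59 to 8.82 ± 3.95 CPM (log2 change -2.13, SE 0.34, edgeR adjusted p = 0.00183) and NANOG from 5.26 ± 0.733 to 1.06 ± 0.678 CPM (log2 change -2.18, edgeR adjusted p = 0.00706). Of 29 pluripotency genes 17 fell and 0 rose, with a median log2 change of -0.98, and 23 fell when adjusted over the list alone (camera adjusted p = 1.23e-14, and adjusted p = 0.329 with an estimated correlation). CDH1 fell from 122 ± 21.3 to 27.6 ± 3.84 CPM, one of 7 of 16 surface epithelium genes that fell with 0 rising (camera adjusted p = 3.75e-06, and adjusted p = 0.486 with an estimated correlation). COL3A1 rose from 63.6 ± 10.8 to 325 ± 69.9 CPM, and 11 of 30 fibroblast and matrix genes rose with 0 falling (camera adjusted p = 1.44e-09, and adjusted p = 0.346 with an estimated correlation).

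SPRY4 fell in light 10 min from 18.8 ± 1.81 to 8.19 ± 1.66 CPM (log2 change -1.22, edgeR adjusted p = 0.000209). Of 25 FGF and ERK targets 2 rose and 3 fell (camera adjusted p = 0.402). SOST rose from 5.91 ± 6.31 to 57.0 ± 13.7 CPM and HESX1 fell from 15.1 ± 6.15 to 0.912 ± 0.512 CPM. EdgeR called 1136 genes, 390 higher and 746 lower in light 10 min, and 521 at 2-fold or more (106 higher and 415 lower). The share of calls that were higher ran from 23.7% at a threshold of 1.5-fold to 46.0% with the low-share libraries only, chosen after seeing the data. The count was 622 and 707 without no FGF2 replicates 1 and 2, and 671, 496 and 494 without light 10 min replicates 1, 2 and 3.

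**Figure D3:**
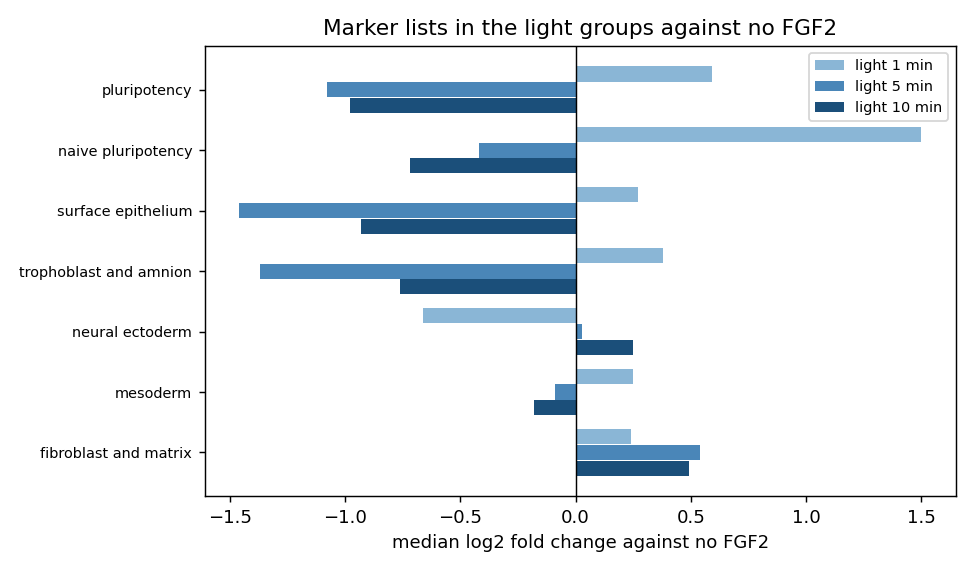
Median log2 fold change of marker lists in each light group against no FGF2, 1 bar per list and light group. The pluripotency median is 0.59, -1.08 and -0.98 in light 1, 5 and 10 min.

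Each light group was also set against FGF2 medium, the culture whose state the light was meant to keep. POU5F1 was lower in each light group, by log2 changes of -1.55, -4.04 and -4.95 in light 1, 5 and 10 min (edgeR adjusted p = 0.00159, 1.23e-07 and 3.93e-08). NANOG differed by -1.91, -3.78 and -4.87 (edgeR adjusted p = 0.000633, 6.84e-07 and 2.07e-07). In the pluripotency list 21, 28 and 28 of 29 genes were lower and 2, 1 and 1 higher, with median log2 changes of -1.10, -2.87 and -2.68. Adjusted over the list alone, 25, 28 and 28 were lower. Camera's adjusted p were 1.09e-09, 3.42e-15 and 2.41e-15, and the adjusted p = 0.391, 0.329 and 0.329 with an estimated correlation. With the low-share libraries only, chosen after seeing the data, 9, 26 and 28 pluripotency genes were lower, and 6, 7 and 10 of the FGF and ERK targets described next.

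SPRY4 was lower than in FGF2 medium by log2 changes of -2.76, -3.03 and -3.37, and DUSP6 by -1.49, -1.28 and -1.39, in light 1, 5 and 10 min (highest edgeR adjusted p of the 6 = 2.12e-07). Of the 25 FGF and ERK targets 14, 11 and 11 were lower and 3, 4 and 5 higher. Camera's adjusted p for that list were 9.25e-06, 0.0423 and 0.0329, and the adjusted p = 0.329, 0.62 and 0.619 with an estimated correlation. The call in light 5 min was lost without its replicate 3 (camera adjusted p = 0.096). EGR1, an immediate early gene, was higher in the 3 light groups, at 27.6 ± 8.36, 23.2 ± 7.70 and 21.4 ± 3.48 CPM against 11.1 ± 2.27 CPM (log2 changes 1.32, 1.07 and 0.96). EGR1 also rose without FGF2, where its libraries were at 34.2, 33.1 and 21.4 CPM, so its rise was not particular to light. Of 20 immediate early genes 10, 13 and 12 were higher and 0, 1 and 4 lower (camera adjusted p = 0.00095, 0.00815 and 0.0396, and adjusted p = 0.457, 0.589 and 0.623 with an estimated correlation). The call in light 10 min was lost without FGF2 medium replicate 2, light 10 min replicate 1 or light 10 min replicate 3 (camera adjusted p = 0.104, 0.0529 and 0.0553).

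PAX6 was higher than in FGF2 medium by 2.72, 3.43 and 3.40 on the log2 scale, and CRYAA, at 0.154 ± 0.127 CPM there, was at 91.9 ± 54.1, 232 ± 83.3 and 45.3 ± 39.2 CPM in light 1, 5 and 10 min. HSD17B2 rose from 0.246 ± 0.0622 to 37.4 ± 11.6, 66.6 ± 10.7 and 45.3 ± 6.45 CPM. EdgeR called 4187, 8142 and 7907 genes in light 1, 5 and 10 min against FGF2 medium, of which 1502, 3120 and 2939 changed at least 2-fold. The first count was 2550 without FGF2 medium replicate 3, and with the low-share libraries only, chosen after seeing the data, the counts were 932, 4099 and 4348.

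**Figure D4:**
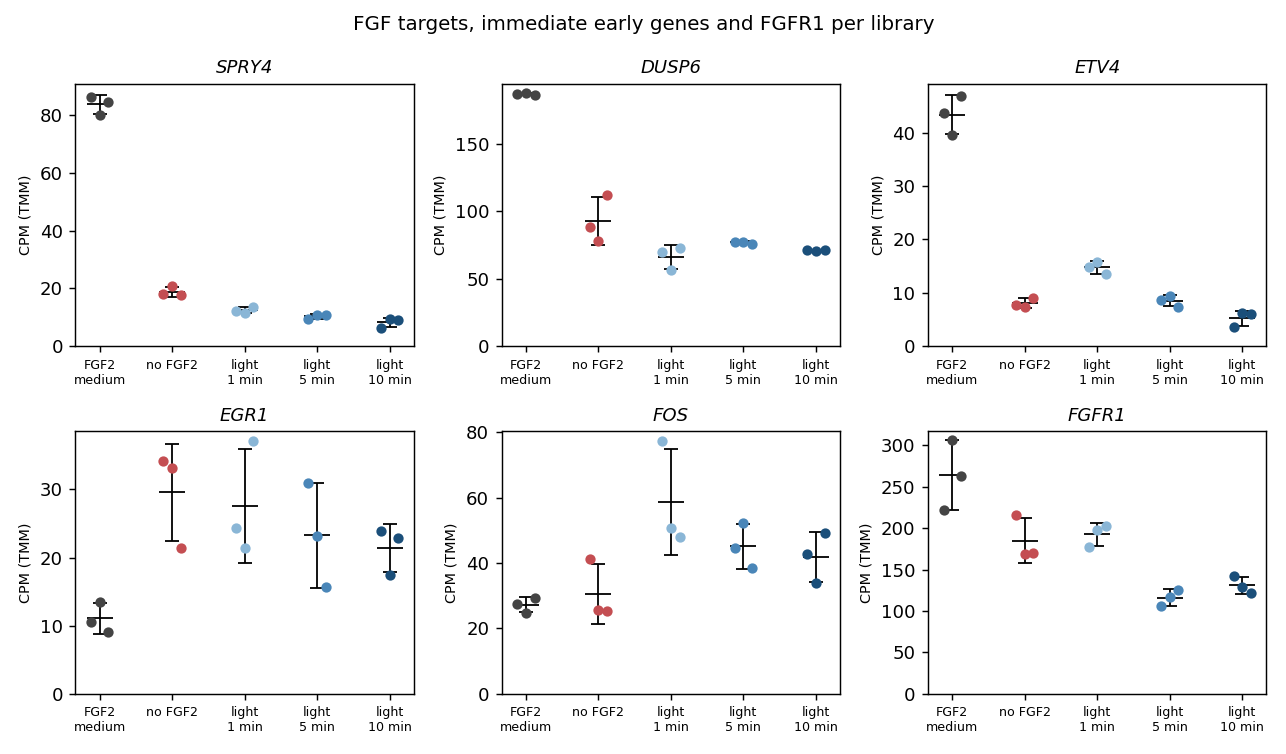
CPM of SPRY4, DUSP6, ETV4, EGR1, FOS and FGFR1 in each library by group, with points for libraries and bars for mean ± SD (n = 3). Mean SPRY4 is 83.6 CPM in FGF2 medium, 18.8 without FGF2 and 12.4, 10.3 and 8.19 in light 1, 5 and 10 min.

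How far the light groups shared the change made by leaving out FGF2 was compared across 18363 genes, which are not independent replicates. Log2 changes against FGF2 medium correlated with those of no FGF2 with Pearson's r of 0.779, 0.808 and 0.834 and Spearman's rho of 0.746, 0.761 and 0.823 in light 1, 5 and 10 min. Since the FGF2 libraries are shared, 20 simulations of unchanged groups gave mean r of 0.481, 0.482 and 0.462. Covariances were 0.575, 0.862 and 0.882 against a simulated 0.046 for each, which leaves 0.528, 0.816 and 0.835, beside a variance of 0.909 for the change without FGF2. No simulated value was taken from this variance, so it still holds sampling noise and is not on a like footing. Genes higher in both comparisons numbered 1684, 2591 and 2714, where independent lists give 463, 821 and 791. Genes lower in both numbered 1652, 2702 and 3045, where independent lists give 427, 909 and 889. Part of the excess may come from the shared FGF2 libraries, which were not divided between the sides because 1 side would keep a single library.

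Of the 7809 genes changed by leaving out FGF2, light 1 min against no FGF2 moved 898 back toward FGF2 medium and 48 further away, where independent lists give 261 and 262. Light 5 min moved 754 back and 864 further, where independent lists give 672 and 670. Light 10 min moved 189 back and 462 further, where independent lists give 242 and 241. The libraries without FGF2 enter both sides of this count, which by itself favours movement back, and were not divided between the sides. The medium label of the light groups lists FGF2, so light and FGF2 cannot be told apart in this movement. The counts were not stable. Those for light 1 min were 211 back and 20 further without its replicate 2, 2330 and 141 without its replicate 3, 325 and 343 back and 25 and 26 further without no FGF2 replicates 1 and 2 in turn, 339 and 35 with library composition as a term, and 226 and 13 with the low-share libraries only. Light 5 min moved 200 and 90 back and 637 and 516 further with these 2 last alternatives, but 1018 back and 648 further without no FGF2 replicate 3, 1065 and 778 without FGF2 medium replicate 2, and 1400 and 1117 without light 1 min replicate 3, so its direction stays open. Light 10 min moved 425 back and 406 further without no FGF2 replicate 3, and fewer back than further in the other recounts. These recounts were chosen after seeing the data.

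The light groups were compared directly. In the pluripotency list 21 of 29 genes were lower in light 5 min than in light 1 min and 0 higher, with a median log2 change of -1.63 (camera adjusted p = 3.54e-20, and adjusted p = 0.327 with an estimated correlation). In light 10 min 22 were lower than in light 1 min and 0 higher, with a median of -1.68 (camera adjusted p = 2.78e-21, and adjusted p = 0.327 with an estimated correlation). CDX4 was at 5.80 ± 2.97 CPM in light 1 min and 0.0127 ± 0.0221 CPM in light 5 min, below the depth floor. H1-1, a linker histone, fell from 35.1 ± 8.52 to 1.47 ± 1.39 CPM in light 5 min, and ZIC4, a neural zinc finger gene, rose from 1.65 ± 0.540 to 9.34 ± 2.59 CPM. For light 5 min against light 1 min edgeR called 2289 genes, 715 of them higher in light 5 min, and for light 10 min against light 1 min 1602, 449 of them higher in light 10 min. The first count was 1211 and 1522 without light 5 min replicates 1 and 2, and the second 917, 977 and 920 without light 10 min replicates 1, 2 and 3.

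Between light 10 min and light 5 min edgeR called 5 genes, each lower in light 10 min, with 1446 at an unadjusted p under 0.05. GJA3, a lens connexin, fell from 4.34 ± 0.504 to 0.728 ± 0.367 CPM, APLN, a peptide ligand, from 7.69 ± 4.26 to 1.82 ± 0.154 CPM and CYP26A1, which degrades retinoic acid, from 23.8 ± 2.33 to 9.62 ± 1.93 CPM. The others were MT2A and PDZD2, named after their values were seen. DESeq2 called 60 genes, 32 higher and 28 lower in light 10 min, and limma-voom 0. The edgeR count was 0 without light 5 min replicate 1 and 16 without its replicate 2, 10 higher and 6 lower in light 10 min. It was 0 without any 1 of the light 10 min replicates, so neither direction prevailed throughout. In the pluripotency list 0 genes rose and 0 fell, with a median of -0.11.

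**Figure D5:**
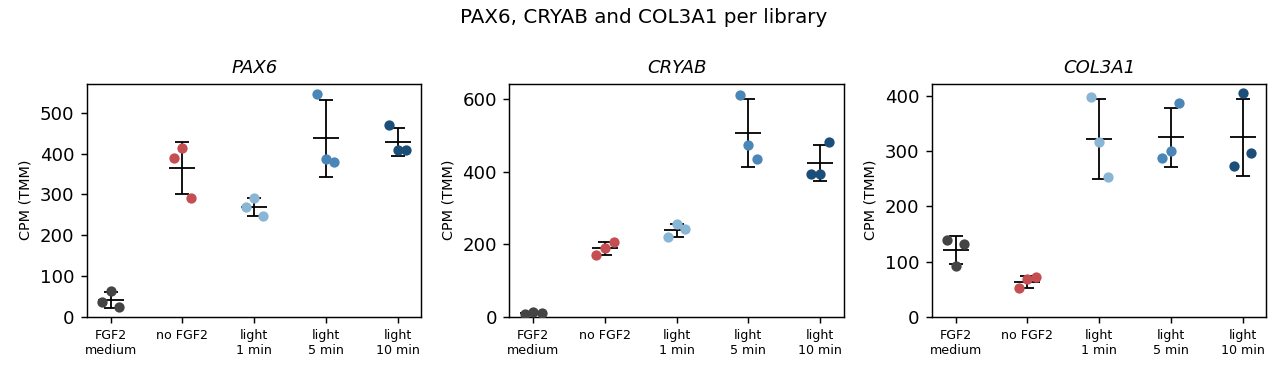
CPM of PAX6, CRYAB and COL3A1 in each library by group, with points for libraries and bars for mean ± SD (n = 3). Mean PAX6 is 40.7 CPM in FGF2 medium and 364 without FGF2, and mean COL3A1 is 63.6 CPM without FGF2 and 322 in light 1 min.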

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

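The tests of library composition, of flow cell and of dilution by other cells were chosen after seeing the result they bear on.

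The change in the light groups against no FGF2 differed between light labels for some genes. Each gene counted as opposite was also called by edgeR between those light groups. Its opposite calls make that nearly certain, so the direct test adds little. The change was called in opposite directions in light 1 min and light 5 min for 73 genes. Of these 71 were higher in light 1 min than without FGF2. For light 1 min and light 10 min this held for 46 genes, each higher in light 1 min. More genes were called in the same direction. In both light 1 and 5 min 230 were higher and 259 lower, where independent lists give 49 and 55. In both light 1 and 10 min 107 were higher and 122 lower, where independent lists give 14 and 23. The shared libraries without FGF2 favour the same direction. Examples of opposite directions, chosen after their values were seen, are PODXL and ZFP42. The log2 changes in light 1, 5 and 10 min were 1.04, -1.14 and -0.98 for PODXL and 0.96, -0.96 and -0.72 for ZFP42.

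The pattern that light 1 min lay nearer to FGF2 medium than light 5 and 10 min was weighed against library composition and flow cell, on the whole pluripotency list in light 10 min against light 1 min. With composition as a term the list's median log2 difference was -1.55, and without the libraries of the second flow cell it was -1.59, beside -1.68 with neither change. Leaving out 1 library at a time gave medians of -1.79 to -1.59. These values argue against either technical difference on its own as the whole cause. They cannot decide on both together, because no light 1 min library matched the light 10 min libraries in both. Light 1 min replicates 1 and 2 had shares over 5%, and replicate 3 came from the second flow cell. The light 10 min libraries had lower shares and came from the first flow cell. A difference in the light treatment may account for the pattern and stays untested, because the labels do not say what the minutes mean.

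The pattern that pluripotency genes were lower in light 5 and 10 min than without FGF2 was weighed likewise. With composition as a term the median in light 5 min was -1.17, beside -1.08 without it. Each library of light 10 min and of no FGF2 was a low-share library, so composition class did not differ between these groups. With low-share libraries only, the median in light 10 min was -0.96, which argues against this class as the cause for light 10 min. If other cell types had gained share evenly, their markers would have risen alike. The trophoblast and amnion list had a median of -1.37 while the fibroblast and matrix list had one of 0.54. These values argue only against such an even gain. A gain of a single other cell type would raise its own markers alone, so they cannot decide on a larger share of matrix-producing cells. Such a share, or a change in cell state, could still account for all or part of the pattern, and RNA from the feeder layer was not tested.

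Whether chance splits of the 6 libraries of each comparison give as many calls cannot be decided, since 10 splits never give a share under 0.05. In each comparison 1 split, the real one, reached its own count. Without FGF2 it gave 7809 genes against a highest other of 2, in light 1 min against no FGF2 1229 against 43, in light 1 min against FGF2 medium 4187 against 1, and between light 10 and 5 min 5 against 2. The highest other was 0 for the remaining 6 comparisons, beside real counts of 3154, 1136, 8142, 7907, 2289 and 1602.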

How the results depend on the processing

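The composition term and the low-share fit were chosen after seeing the data. For called named genes, 14690 results under the alternatives kept their call and direction, 1529 kept the direction but not the call and 0 reversed. Apart from the genes always taken, these genes were picked for large or clear changes in the same data, which favours stability. Alternatives that filtered a gene out are not counted for it. Of the 127 called list tests 0 held with an estimated correlation, 94 with fry, 103 with the composition term and 90 with low-share libraries. Unless a sentence gives a cause, the cause was not tested.

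The following counts moved by over 1.5 times. With a mean of at least 10 CPM, where fewer genes are tested, no FGF2 against FGF2 medium gave 5005, light 10 min against no FGF2 606, light 1, 5 and 10 min against FGF2 medium 2732, 5110 and 5118, light 5 and 10 min against light 1 min 1465 and 1020, and light 10 against 5 min 0. With no low count filter light 1 and 10 min against no FGF2 gave 2709 and 2016, light 10 against 1 min 2406 and light 10 against 5 min 579. A threshold of 1.5-fold (glmTreat), stricter by construction, gave 1710 for no FGF2 against FGF2 medium, 51, 374 and 169 for light 1, 5 and 10 min against no FGF2, 977, 2813 and 2500 against FGF2 medium, 528 and 399 for light 5 and 10 min against light 1 min, and 0 for light 10 against 5 min.

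The composition term gave 530 and 1680 for light 1 and 5 min against no FGF2. Low-share libraries, which are fewer, gave 462 and 1482 there, 2964 for no FGF2 against FGF2 medium and 932, 4099 and 4348 for light 1, 5 and 10 min against it. Light 1 min against no FGF2 gave 1903 with a flow cell term, 2042 without the second flow cell, 2078 with DESeq2 and 287 with only its groups fitted, and light 1 min against FGF2 medium 2763 with only its groups. Light 10 against 5 min gave 2 with RLE factors, 2 with at least 1 CPM in 3 libraries, 2 with the composition term, 34 with low-share libraries, 28 with only its groups, 60 with DESeq2, and 0 with limma-voom, the flow cell term and the replicate block.

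Leaving out 1 library of the groups compared gave 5460 to 7943 for no FGF2 against FGF2 medium. Light 1, 5 and 10 min against no FGF2 then gave 299 to 3463, 1889 to 3109 and 494 to 1358. Against FGF2 medium they gave 2550 to 4455, 6633 to 7928 and 6238 to 7971. Light 5 and 10 min against light 1 min gave 1211 to 2161 and 917 to 2109, and light 10 against 5 min 0 to 16. Libraries of other groups also moved counts through the shared fit. Without light 1 min replicate 3, no FGF2 against FGF2 medium gave 8710. Light 5 and 10 min against no FGF2 then gave 4533 and 1680. Leaving out any 1 library gave 118 to 131 called list tests. The correlations with the change without FGF2 were 0.874, 0.858 and 0.906 at a mean of at least 10 CPM, and ran 0.761 to 0.812, 0.799 to 0.825 and 0.823 to 0.85 with 1 FGF2 library left out. The called direction of the mitochondrially encoded list in light 10 against 1 min reversed with both added alternatives. Its median log2 change was -0.17 with the composition term and -0.45 with low-share libraries. In light 10 against 5 min the called directions of that list and of the oxidative phosphorylation list reversed with the composition term. Their medians were then -0.09 and 0.04.

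Replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at -0.244 to 0.256, 0 of 10 group pairs had every r over 0.1, and 3 of 15 libraries correlated best with their own number. With the replicate block no FGF2 against FGF2 medium gave 7246 and light 1, 5 and 10 min against no FGF2 891, 2614 and 914. Depth limits genes near the floor of 0.0803 to 0.271 CPM.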

Other observations

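The list of eye genes was chosen after CRYAA, CRYAB, FOXE3 and PAX6 had been seen to rise, while its test was set before the values of the genes it counts were seen.

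Several groups of housekeeping and stress genes fell without FGF2. Of 30 nuclear genes of oxidative phosphorylation 25 fell and 0 rose, with a median log2 change of -0.52 (camera adjusted p = 6.79e-08, and adjusted p = 0.486 with an estimated correlation). Of 30 ribosomal protein genes 20 fell (camera adjusted p = 1.99e-06, and adjusted p = 0.384 with an estimated correlation). Of 24 p53 targets 16 fell, with AEN going from 195 ± 44.6 to 81.4 ± 13.1 CPM (camera adjusted p = 0.000124, and adjusted p = 0.63 with an estimated correlation). Against no FGF2 7, 8 and 1 of them rose and 0 fell in light 1, 5 and 10 min, with CDKN1A going from 136 ± 25.9 to 234 ± 8.11 CPM in light 5 min (camera adjusted p = 1.34e-05, 5.51e-06 and 3.44e-05, and adjusted p = 0.619, 0.619 and 0.623 with an estimated correlation). Of 18 circadian clock genes 0 rose and 1 fell in light 1 min against no FGF2 (camera adjusted p = 0.664).

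A hypothesis from the rise of CRYAA, CRYAB, FOXE3 and PAX6 is that cells without FGF2 may express an eye field or lens-like programme. It was tested on a list of 27 eye field and lens genes, of which 26 were tested. Genes whose values had been seen before the prediction, CRYAA among them, were left out, and of the other 15 genes 14 rose without FGF2 and 0 fell, a share of 93.3%. PROX1 went from 3.55 ± 0.755 to 31.7 ± 9.89 CPM, MAF from 25.6 ± 8.79 to 92.1 ± 24.5 CPM, and RAX from 6.16 ± 3.33 to 47.3 ± 29.1 CPM. CRYBB1, at 19.5 ± 19.3 CPM, and CRYBA1, at 14.5 ± 13.6 CPM without FGF2, had SDs close to their means, and the CRYAA libraries were at 2.30, 79.6 and 202 CPM. Against FGF2 medium PROX1 was higher by 3.18 on the log2 scale without FGF2 and by 3.02, 3.66 and 3.09 in light 1, 5 and 10 min, and PITX3 by 3.46 and by 3.65, 4.62 and 3.94. Others that rose without FGF2 were not called in light. SIX3 was higher by 1.34 without FGF2 and by 0.06, 0.15 and 0.47 in light 1, 5 and 10 min (edgeR adjusted p = 0.877, 0.587 and 0.0793). PAX2 was higher by 3.23 and by 1.97, 2.25 and 1.61 (edgeR adjusted p in light = 0.166, 0.0699 and 0.224). MIP was higher by 2.88 and by 1.87, 2.05 and 0.77 (edgeR adjusted p in light = 0.161, 0.0777 and 0.58). Standard errors of PAX2 and MIP in light were 0.91 to 1.04, so a rise of these 2 there is not excluded. These genes were chosen after their values were seen. PAX6, at 364 ± 63.8 CPM without FGF2, is also expressed in neural ectoderm and stands in that list, as do OTX2, SIX3, SIX6, LHX2 and HES5. CRYAB, at 189 ± 18.0 CPM, stands in the list of heat shock proteins, MITF in that of neural crest and TBX3 in that of mesoderm. The values are consistent with such a programme, but they were found and tested on the same libraries and no cell type was identified.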
